A study of Mus musculus with 11 samples.

How the data were processed

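Chromatin immunoprecipitation with an antibody to GFP was followed by sequencing of 11 libraries from mouse neural stem cells, either homozygous for a Smchd1-GFP knock-in allele or wild-type, with whole cell extract as input. Chromatin was cross-linked with formaldehyde and fragmented by 30 min of sonication in non-ionic detergent in 6 libraries and by micrococcal nuclease in 5, per the labels' protocols. Groups were taken from the library titles: for sonication, 2 knock-in, 2 wild-type and 2 whole cell extract libraries from female cells; for MNase, 1 male and 1 female knock-in library, 1 male and 1 female wild-type library and 1 female whole cell extract library.

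The tools bcl2fastq, Bowtie 0.12.9 and MACS2 and the genome build mm10 are named per the submitters' processing notes, without a role or order and without a version for bcl2fastq and MACS2. The authors deposited 3 tables: a peak list for each experiment and a list of broad domains. The labels of all libraries of an experiment name the same peak list, so each list was treated as pooled; how the wild-type and whole cell extract libraries entered it is not given in the sources used here. Per the file headers, the peak lists have the layout of an annotated probe report, and the cells of the MNase list name SeqMonk as the origin of the peaks. The only values used from them were the start and end of each peak in base pairs. All peaks start on a grid of 150 bp and are at least 300 bp wide, and the value column was empty in every row. Peak positions therefore depend on the window of the caller, and widths carry steps of 150 bp. The deposited domain list has no header; its name points to the domain caller EDD, and its boundaries lie on a grid of 5 kb. The authors' score per domain in that list is on a scale not given in the sources used here and was used only to rank domains.

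Reads per library, fold enrichment and scores per peak were not analysed here, so the depth of each library and the spread between replicates were unknown. The tests of knock-in against wild-type read counts planned before the data were examined could not be run. Peak width, chosen after the files were seen, took the place of fold enrichment in the comparison of X and autosomal peaks, as a mean in place of a median, and in choosing which genes to name. For a stricter threshold, the list was limited to peaks wider than 300 bp. No library, group or replicate was compared with another by a test, and the p-values describe how peaks are placed in a list.

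Genes came from a RefSeq table of the same assembly as mm10, which gives spans without strand, exons or transcription start sites. The planned promoter test was therefore replaced by the distance to either boundary of a coding gene, and no exon or intron is stated. In this table, 340 records within the first 3 Mb of a chromosome, an assembly gap, were left out, and 49603 records, 21779 of them coding, were used. Chromosome length ran from the end of the gap to the last gene or peak, which made the X 168 Mb and 6.52% of the length of the 19 autosomes and the X. Y was left out of shares.

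The X share of peaks was tested against its share of length with an exact two-sided binomial test, with 95% Wilson intervals, and the shares of both lists were compared with Fisher's exact test. Peaks at gene boundaries (within 1 kb), in genes, in domains and in the other list (overlap of at least 1 bp) were compared with 10000 circular rotations of the peaks within each chromosome, which keep their number and spacing. This is a permutation test of positions, and p-values from it are called permutation p. The smallest p these can give is 0.0001 one-sided and 0.0002 two-sided. For 13 gene lists fixed before the data were examined, members with a peak within 5 kb were counted against the same kind of rotation, one-sided for more members, with Benjamini-Hochberg adjustment over the 13 lists in each peak list. Of the imprinted genes, 46 of 47 names were found in the gene table; all names of the other lists were found. Widths were compared with 100000 permutations.

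Genes were named by a rule fixed before the data were examined: those at the 15 highest peaks of each list (here the widest; the gene overlapped or the nearest within 50 kb), the 10 genes with the most peaks within 5 kb, up to 4 members of each fixed list by their highest peak (here widest), every domain with its fixed-list genes, and Smchd1. Some genes the rule selects are not reported here. Ties in width were taken in chromosome order for peaks and in alphabetical order for members of a list. Predicted genes were passed over where another gene was at the same peak. Genes at shared peaks and at MNase peaks on the X, and Tsix, Hoxd1 and Hoxc4, were named after their values were seen.

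The rotation tests were tested on simulated data over 1546 genes with 500 rotations each. Simulated peaks kept the number per chromosome and the widths of each list and were placed at random. The gene lists tried were developmental regulators, neural stem cell, imprinted and housekeeping genes and olfactory receptors, and the other fixed lists were not simulated. Of 500 tests of these lists, 2.2% had a p under 0.05 with peaks simulated for the MNase list and 2% for the sonication list. With peaks planted at 10 developmental regulators, 100% of 100 tests did for both. Smaller numbers of planted genes were not tried. For gene boundaries on chromosome 1 and the X, 4% of 100 simulated peak sets and 100% of 100 sets with planted boundary peaks did, for both. Simulated peaks did not cluster or favour genes as real peaks can, so these rates need not hold for the real lists. Alternatives tried were merging of peaks within 100 kb, base pairs in place of peaks, an X copy number of 0.75, boundary distances of 5 kb, boundaries of all genes, coding genes only, gene bodies alone or a window of 50 kb, peaks wholly inside domains, overlap of at least 0.5 of both peaks or within 10 kb, and several chosen after the data were seen: wider peaks, autosomes and X apart, peaks outside the Hox clusters, and domains with the upper scores. Computation used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and matplotlib 3.10.9 for figures.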

Results

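Binding of Smchd1 was mapped by chromatin immunoprecipitation and sequencing in neural stem cell lines that had been derived from C57BL/6 mouse embryos. Smchd1 is a chromatin protein of the SMC family, known for its part in silencing genes on the inactive X chromosome and at some autosomal gene clusters. The protein carried a GFP tag from a homozygous knock-in allele and was pulled down with an antibody to GFP. Wild-type cells without the tag, put through the same pull-down, and whole cell extract served as controls. The 11 libraries formed 6 groups. In the sonication experiment, all 6 libraries came from female cells, 2 from knock-in cells, 2 from wild-type cells and 2 from whole cell extract. In the experiment with micrococcal nuclease (MNase), the knock-in and the wild-type group each held 1 male and 1 female library, and whole cell extract was represented by 1 female library. Each experiment was summarised by the authors as 1 list of peak positions, so no value per library, replicate spread or sequencing depth was known for any peak. The statistical tests therefore describe peaks within a list, which are not biological replicates, and intervals cover counting error only.

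The sonication experiment asked whether Smchd1 binds the inactive X, with long sonication used to free its compact chromatin. Peaks were concentrated on the X. Positions alone do not tell the inactive X from the active X, and no male library was sonicated. Of the 2195 sonication peaks on the autosomes and the X, 549 lay on the X, a share of 25.0% (95% Wilson interval 23.2% to 26.9%), where the length of the X gave 6.52%. The X held 3.27 peaks per Mb and the autosomes 0.685 peaks per Mb, a ratio of 4.78. Among autosomes the density ran from 0.467 peaks per Mb on chromosome 8 to 0.846 on chromosome 6. The excess on the X was larger than counting error by an exact two-sided binomial test (p = 2.87e-165). With neighbouring peaks no more than 100 kb apart merged, the X share was 18.7%. Nearby peaks are not independent, so the p-value of the unmerged list is too small.

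**Figure D1:**
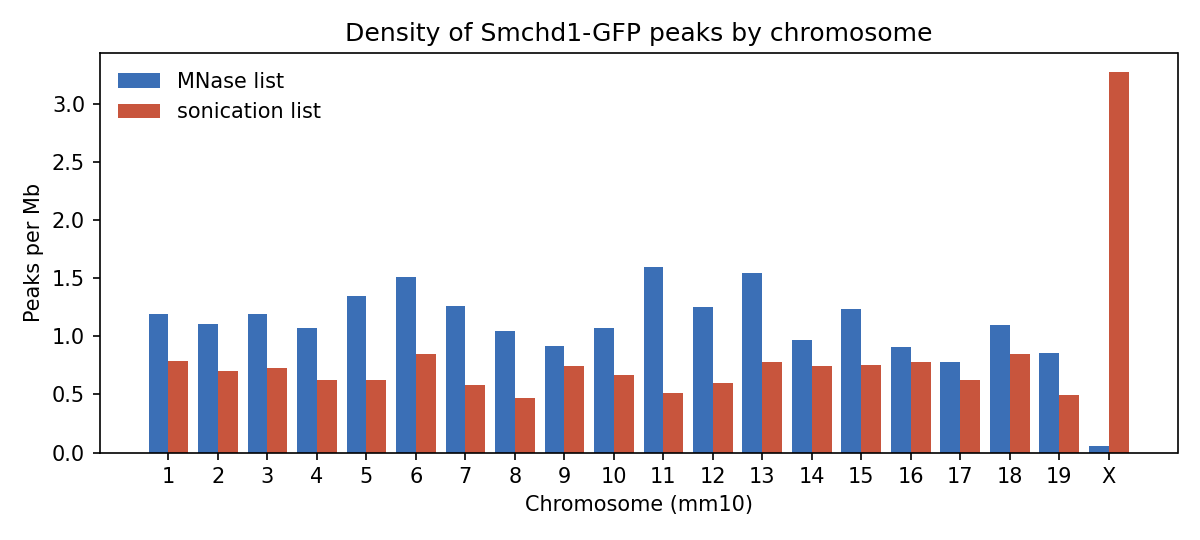
Peaks per Mb on each autosome and the X of mm10, with 1 bar for the MNase list and 1 for the sonication list; the lists pool libraries, so there are no error bars. The X has the highest density of the sonication list, 3.27 peaks per Mb, and the lowest of the MNase list, 0.0596 peaks per Mb.

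Dmd, the dystrophin gene, from 82814664 to 85205050 on X in mm10, held or adjoined 18 sonication peaks, more than any other gene. Eda, which encodes the ectodysplasin signal of skin appendages, had 9 and Il1rapl1, a synaptic adhesion gene, had 8. Efhc2 had 5 peaks, and Fgf13, which encodes an intracellular fibroblast growth factor homologue, and Il1rapl2 had 4 each. These 6 X-linked genes were among the 10 genes with the most sonication peaks. The other members of that group were Hoxa10 with 4 peaks and 3 long autosomal genes, Gpc5 and Nrxn3 with 5 each and Csmd1 with 4. Gpc5 encodes a glypican, Nrxn3 a presynaptic neurexin and Csmd1 a large membrane protein with complement-control domains. Gene length differed widely in this group: counted with 5 kb on each side of the gene, Dmd had 7.50 peaks per Mb, Eda 20.7, Efhc2 25.3, Nrxn3 3.08 and Hoxa10 203.

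Peaks on the X were wider than those on autosomes in the sonication list. Their mean width was 412 bp ± 176 (SD, 549 peaks) on the X and 378 bp ± 174 (SD, 1646 peaks) on autosomes (two-sided permutation test, p = 0.00014). In the list as a whole, 66.6% of peaks had the smallest width, 300 bp. The widest on the X, 2.25 kb from 83601601 to 83603850, lay in Dmd.

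The X-inactivation centre had no sonication peak within 5 kb of any of its 10 genes, where rotation of the peaks along the chromosomes gave a mean of 1.32. Within 50 kb, 2 of the 10 genes had one, with a rotated mean of 3.23. Xist, whose RNA coats the inactive X, and its antisense partner Tsix, from 103431517 to 103484957, had 0 peaks. Of the loci with tandem repeats, Firre, a long non-coding RNA gene, held 1 peak of 900 bp, from 50598301 to 50599200, and 4933407K13Rik held 0 (adjusted permutation p = 1 for the pair). Among genes known to escape X inactivation, 3 of 13 had a peak: Mid1, a ubiquitin ligase gene near the end of the X, had 3 peaks, and Kdm6a, a histone demethylase gene, and Shroom4, an actin-binding protein gene, had 1 each. The rotated mean for this list was 2.56 genes (adjusted permutation p = 1), so none of the lists of X genes passed the test.

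Broad domains of enrichment covered most of the X. The authors' domain list held 11 domains, of which 8 were on the X, and 98.3% of the domain length lay there. The X domains added up to 111.3 Mb, or 66.4% of the X beyond its first 3 Mb. The longest ran from 54945001 to 94875000, over 39.9 Mb, and held Eif2s3x, a translation factor gene that escapes inactivation, Sox3, a neural stem cell gene, and 4933407K13Rik. It also had the highest authors' score, 121.7, on a scale not stated. The next, of 29.6 Mb from 94985001 to 124630000, had a score of 82.9 and held every gene of the X-inactivation centre list, Xist and Tsix included. A domain of 15.6 Mb from 37840001 to 53460000 held Firre and Utp14a, and one of 11.3 Mb from 13475001 to 24805000 held Kdm6a. The other X domains, of 6.66, 4.51, 1.93 and 1.71 Mb, held none of the fixed-list genes except members of the olfactory and vomeronasal receptor families. The first 10.5 Mb and the last 18.8 Mb of the X had no domain. The domains outside the X measured 0.385 Mb on chromosome 12, 1.43 Mb on chromosome 13 and 0.165 Mb on Y. No test was made of the length covered.

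**Figure D2:**
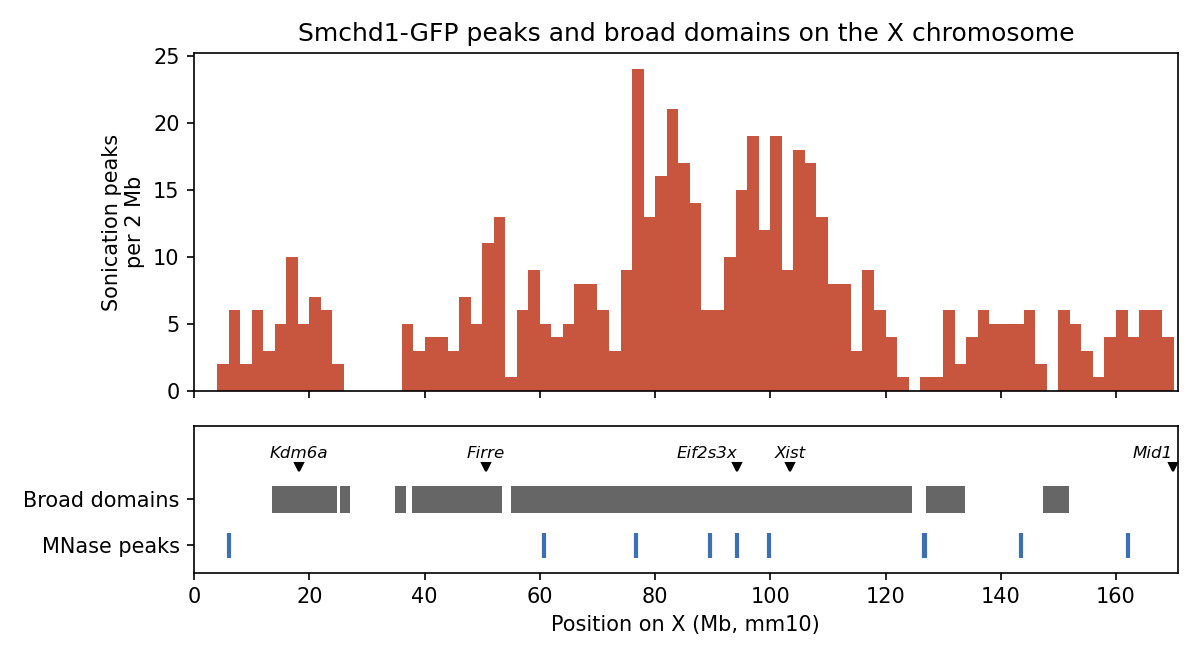
Sonication peaks in 2 Mb bins along the X (top, position in Mb of mm10) with the deposited broad domains as grey bars, the MNase peaks as ticks and selected genes as triangles (bottom). The fullest bin, from 76000001 to 78000000, holds 24 peaks and lies in the longest domain; the stretch between domains from 27005001 to 34815000 holds 0.

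Sonication peaks clustered in these domains. Of the 549 on the X, 456 (83.1%) lay inside a domain, with 4.10 peaks per Mb inside and 1.65 per Mb outside, a ratio of 2.48. Circular rotation of the X peaks gave a mean of 364 inside (two-sided permutation p = 0.007). Over all chromosomes, the observed 456 compared with a rotated mean of 367 (two-sided permutation p = 0.0154). Coding genes were sparser inside the domains, at 4.74 per Mb, than outside, at 7.65 per Mb. The largest domain held 193 sonication peaks and the one with Xist 159, while the domain from 25300001 to 27005000 held 0. Both the domains and the peaks were called by the authors, and if both came from the same reads, the agreement in position is not independent.

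Sonication peaks at the ends of coding genes were no more frequent than rotated peaks when the whole list was counted. Of 2195 peaks, 59 (2.69%) came within 1 kb of a boundary of a coding gene, with a rotated mean of 72.4 (two-sided permutation p = 0.122). Within 5 kb, 183 peaks compared with 264 rotated, below chance (two-sided permutation p = 0.0002, the smallest the rotations can give). Among peaks wider than 300 bp, in contrast, the 38 at boundaries exceeded the rotated 25.5 (two-sided permutation p = 0.0246). All 23 sonication peaks in the Hox clusters were among the wider ones. The boundary test was not run without them, so this excess may rest on the Hox clusters. For gene bodies, 959 peaks (43.7%) overlapped a gene, with a rotated mean of 996 (two-sided permutation p = 0.187). The autosomes and the X went opposite ways: 742 autosomal peaks overlapped a gene, fewer than the rotated 818 (two-sided permutation p = 0.0004), and 217 X peaks did, more than the rotated 178 (two-sided p = 0.022). With Dmd, Eda and Il1rapl1 cut out of the X, 182 of 514 peaks overlapped a gene, with a rotated mean of 158 (one-sided permutation p = 0.0761), and the excess on the X no longer passed the test. The difference between the X and the autosomes was not tested.

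Hox clusters were the autosomal sites that stood out in the sonication list. Within 5 kb, 25 of the 39 Hox genes, which encode homeobox transcription factors that pattern the body axis, had a sonication peak, with a rotated mean of 0.488 (one-sided permutation p = 0.0001, the smallest possible; adjusted permutation p = 0.0013 over 13 lists). The widest sonication peak of all, 3.15 kb from 52210951 to 52214100 on chromosome 6, overlapped the long span of Hoxa3 and lay between Hoxa6 and Hoxa7. Others of the widest were at Hoxa9, Hoxb6, Hoxd10 and Hoxd11, Hoxb8, Hoxa10, Hoxc10, Hoxa5 and Hoxa11, and 10 of the 15 widest lay in a Hox cluster. The remaining ones were in Dmd, in the prohormone convertase gene Pcsk2 (1.80 kb), near the pseudogene Vmn2r-ps20 (1500 bp), 4805 bp from the Iroquois homeobox gene Irx2 (1.35 kb) and in the homeobox gene Msx1 (1.20 kb). Peaks at Celf4 and Nr2f2, also of 1.20 kb, tied with the last of these. None of the other lists passed the test with adjustment. No sonication peak lay within 5 kb of the 30 developmental regulators, the 58 clustered protocadherins, the 23 neural stem cell genes, the 12 neuron and glia genes, the 20 housekeeping genes or the 8 Y-linked genes. The rotated means were 0.789, 4.39, 0.527, 0.985, 0.182 and 0.0055, and a one-sided test for more members cannot show fewer, so these zeros are no contrast with the MNase list. Imprinted genes had a peak at 4 of 46 members, Grb10, Snrpn, Kcnk9 and Sgce, with a rotated mean of 1.93 (adjusted permutation p = 0.862). Olfactory receptors had one at 14 of 1427 members and vomeronasal receptors at 5 of 638 (adjusted permutation p = 1 for both).

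The MNase experiment asked where Smchd1 binds on the autosomes. Its list held 2828 autosomal peaks, 10 on the X and 2 on Y. The X share was 0.352% (95% Wilson interval 0.192% to 0.647%), below the 6.52% given by length (exact two-sided binomial test, p = 3.32e-67). The autosomes had 1.18 peaks per Mb and the X 0.0596 per Mb, which is 19.7 times fewer. Autosomal density ran from 0.784 peaks per Mb on chromosome 17 to 1.60 on chromosome 11. The X peaks included 1 that overlapped the claudin-family gene Cldn34d, 1 that overlapped Nhs, the gene of Nance-Horan syndrome, and 1 that lay 250 bp from Eif2s3x. Of these 10 peaks, 5 lay inside a broad domain; over all chromosomes 6 MNase peaks did, with a rotated mean of 9.27 (two-sided permutation p = 0.362). The X peaks had a mean width of 375 bp ± 127 (SD, 10 peaks) and the autosomal peaks 620 bp ± 803 (SD, 2828 peaks), a difference that did not pass the test (two-sided permutation test, p = 0.118). Male cells carry 1 X, and the lists of the sexes were not separate, so the share for female cells alone is unknown.

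The X share differed between the experiments by 24.7 percentage points, 25.0% in the sonication list and 0.352% in the MNase list (Fisher's exact test, two-sided, p = 8.15e-199). With neighbouring peaks merged, the shares were 18.7% and 0.483%. Fragmentation and the sex of the cells changed together between the experiments, and the lists cannot separate them.

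MNase peaks covered large parts of the 4 Hox clusters. In HoxA, from 52155367 to 52260880 on chromosome 6, 29 peaks covered 82.0% of the cluster. In HoxD, from 74668225 to 74765142 on chromosome 2, 26 peaks covered 70.1%. In HoxC, from 102921131 to 103036856 on chromosome 15, 49 peaks covered 60.8%, and in HoxB, from 96194316 to 96368254 on chromosome 11, 55 narrower peaks covered 31.5%. Together the clusters held 159 peaks and 15.9% of all bases in MNase peaks. Of the 39 Hox genes, 38 had a peak within 5 kb, with a rotated mean of 0.660 (one-sided permutation p = 0.0001, the smallest possible; adjusted permutation p = 0.00065). The exception was Hoxd1. The peak over Hoxa9 and Hoxa10 was 13.8 kb wide and the one from Hoxa3 to Hoxa7 13.1 kb. The one over Hoxd11 and Hoxd10 was 12.9 kb wide and the one over Hoxd9 and Hoxd8 11.9 kb. The named HoxA peaks adjoined with no gap, as did other neighbouring peaks in the clusters. Widths and numbers of peaks thus depend on where a continuous stretch was split in the list. Hoxb3, Hoxd3, Hoxa3, Hoxb6, Hoxb7 and Hoxb8 were among the 10 genes with the most MNase peaks, with 21, 19, 17, 12, 11 and 11. The annotated spans of Hoxb3, Hoxd3 and Hoxa3, of 40.8, 36.3 and 44.0 kb, contain other Hox genes. Counted with 5 kb on each side, these 6 genes had 413, 411, 315, 640, 755 and 691 peaks per Mb, in the same order. Hoxc4 and Hoxc6, with 11 peaks each, tied with Hoxb7 and Hoxb8 but fell outside the 10.

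**Figure D3:**
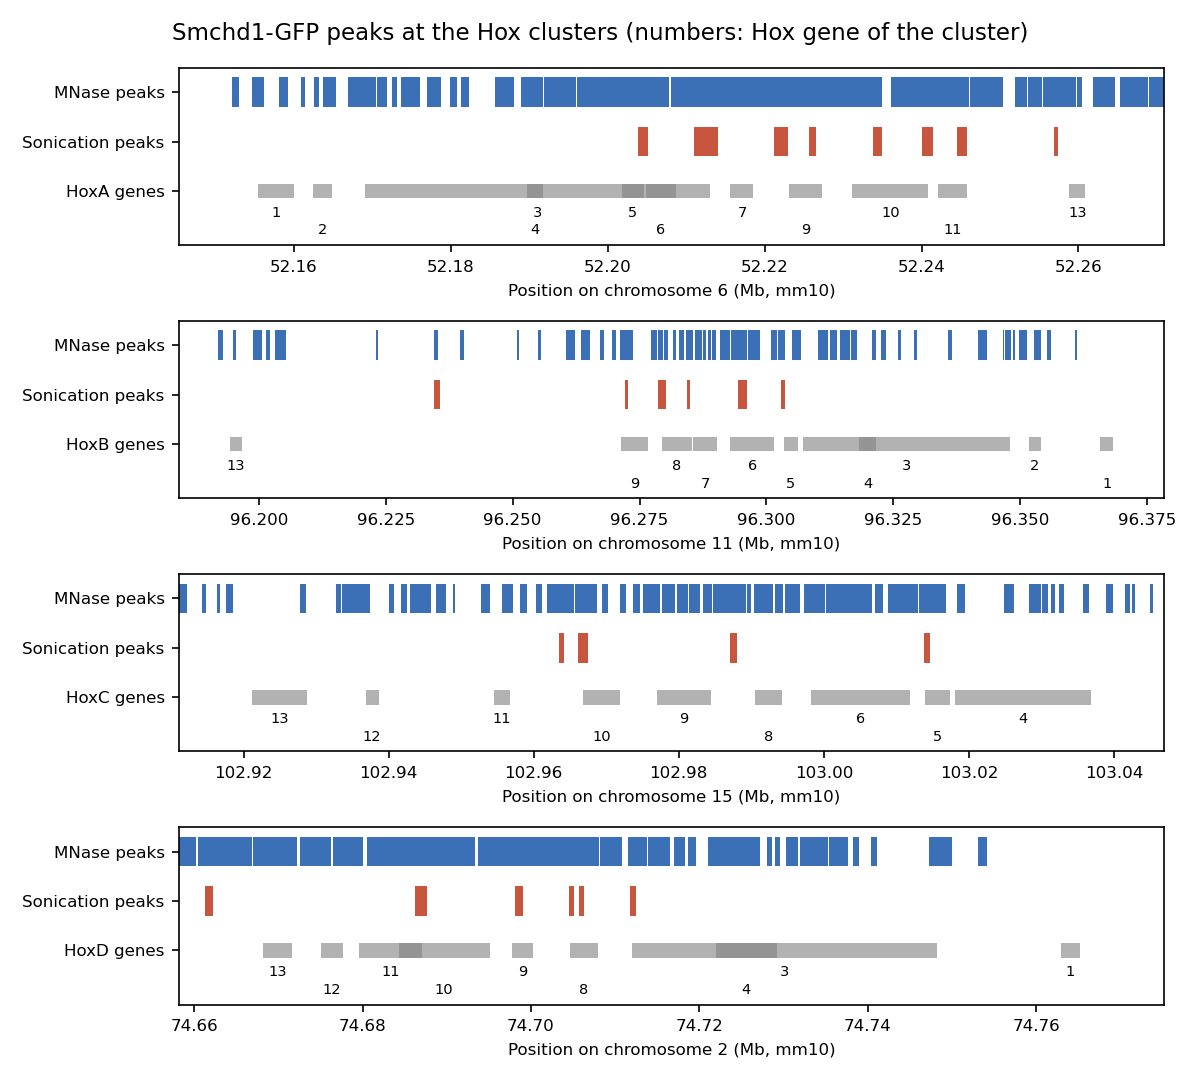
Positions of MNase peaks, sonication peaks and Hox genes (grey bars, with the gene's number) at the HoxA, HoxB, HoxC and HoxD clusters, each with its position in Mb of mm10. MNase peaks cover 82.0%, 31.5%, 60.8% and 70.1% of the clusters, and sonication peaks 10.8%, 3.62%, 3.37% and 4.64%.

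Other genes with many or wide MNase peaks included developmental transcription factor genes. Tfap2a, a transcription factor of neural crest and skin, had 15 peaks and the non-coding transcript Hoxb5os had 14. The widest peak of the list, 16.2 kb from 3184051 to 3200250 on chromosome 11, lay in Sfi1, whose product binds centrin at centrosomes. Nr2f2, the gene of an orphan nuclear receptor, carried one of 7.95 kb, and Evx2, a homeobox gene beside HoxD, carried peaks of 6.45 and 4.80 kb. Further wide peaks lay in Rn18s-rs5, a ribosomal RNA sequence (6.15 kb), in Hjurp, the gene of a centromere histone chaperone (6.00 kb), 1398 bp from Hottip, a non-coding RNA gene at the edge of HoxA (5.85 kb), and in the predicted gene Gm32498 (5.10 kb). No peak was removed here for lying in repeated sequence. Whether the wide peaks at Sfi1 and Rn18s-rs5 mark binding or repeated sequence was therefore not tested.

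Developmental regulators, chosen as typical Polycomb targets before the data were examined, had MNase peaks at 14 of 30 members, with a rotated mean of 1.06 (one-sided permutation p = 0.0001, the smallest possible; adjusted permutation p = 0.00065). The widest at Nkx6-1, a homeobox gene of ventral neural progenitors and beta cells, was 4050 bp wide. Pax3, a paired-box gene of neural crest and muscle, had 9 peaks of up to 1.95 kb, and Gata4, a heart and endoderm factor, had 7 of up to 1500 bp. Tbx3, a T-box gene of limb and heart, had 2 peaks, the wider also of 1500 bp. The 14 genes lay on 8 chromosomes and accounted for 55 peaks. The sonication list had 0 at these genes, with a rotated mean of 0.789, and the difference between the lists was not tested.

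Imprinted genes, which are expressed from 1 parental copy, had MNase peaks at 9 of 46 members, with a rotated mean of 2.53 (one-sided permutation p = 0.0013; adjusted permutation p = 0.00563). Of these, 7 were on chromosome 7, several of them in the same region as Snrpn and some with the same peak. The members with a peak were thus not all separate sites. Snrpn, the paternally expressed splicing gene of the Prader-Willi region, had 5 peaks of up to 1500 bp, and Mkrn3 in the same region had 1 of 450 bp. The annotated span of Snrpn is long, from 59982495 to 60450177. Its widest peak, from 60243601 to 60245100, lay far from both boundaries. Grb10, a growth-restraining adaptor gene on chromosome 11, had 1 peak of 900 bp and Nnat, the neuronatin gene on chromosome 2, 1 of 450 bp. Counting gene bodies without the flanking 5 kb left 6 members, 2.78 times the rotated mean compared with 3.56 times with the flanks (one-sided permutation p = 0.0232, adjusted permutation p = 0.101). The rotations do not allow for the general excess of MNase peaks near genes, for this list or the others. At coding gene boundaries that excess was 4.47 times the rotated mean. Of all 21779 coding genes, 1151 had an MNase peak in the gene or within 5 kb.

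Neural stem cell genes had MNase peaks at 4 of 23 members, Sox2 and Dlx2 among them, with a rotated mean of 0.699 (one-sided permutation p = 0.0031; adjusted permutation p = 0.0101). Sox2 maintains neural progenitors, and Dlx2 directs the formation of forebrain interneurons. Both had 2 peaks each, of up to 750 bp. The count was 5.72 times the rotated mean. Within the gene bodies alone 2 members had a peak, 3.82 times the rotated mean (adjusted permutation p = 0.299). The housekeeping genes, the control for unspecific pull-down, had a ratio of 7.52 from 2 members, no lower than the ratios of the neural stem cell and imprinted lists, and passed among peaks wider than 300 bp (adjusted permutation p = 0.0338). With gene bodies alone, 0 of the 20 housekeeping genes had a peak. Within 50 kb their ratio was 1.23 (adjusted permutation p = 0.778). Neural stem cell genes then had a ratio of 3.54 (adjusted permutation p = 0.00607) and imprinted genes 2.85 (adjusted permutation p = 0.0104). Markers of neurons and glia had a peak at 1 of 12 members, Rbfox3, which encodes the neuronal antigen NeuN (rotated mean 0.791, adjusted permutation p = 0.855).

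The other lists did not pass the adjusted test in the MNase data. Clustered protocadherins, neuronal adhesion genes that lie in tandem on chromosome 18, had a peak at 14 of 58 members, of which 13 were in the alpha cluster and 1 was Pcdhb2. The rotated mean was 4.85 (adjusted permutation p = 0.309), and these members shared 8 peaks, none wider than 450 bp. Abundantly transcribed housekeeping genes, kept as a control for unspecific pull-down, had one at 2 of 20 members, Hspa8 and Rpl13a, with a rotated mean of 0.266 (one-sided permutation p = 0.0305; adjusted permutation p = 0.0793). Eif2s3x was the 1 of 13 escape genes with a peak (adjusted permutation p = 0.12). Olfactory receptors had a peak at 20 of 1427 members (adjusted permutation p = 0.376) and vomeronasal receptors at 5 of 638 (adjusted p = 1). The X-inactivation centre, the X tandem-repeat loci and the Y-linked genes had 0 (adjusted permutation p = 1 for each). Smchd1 itself, from 71344489 to 71475366 on chromosome 17, had 0 peaks in both lists.

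**Figure D4:**
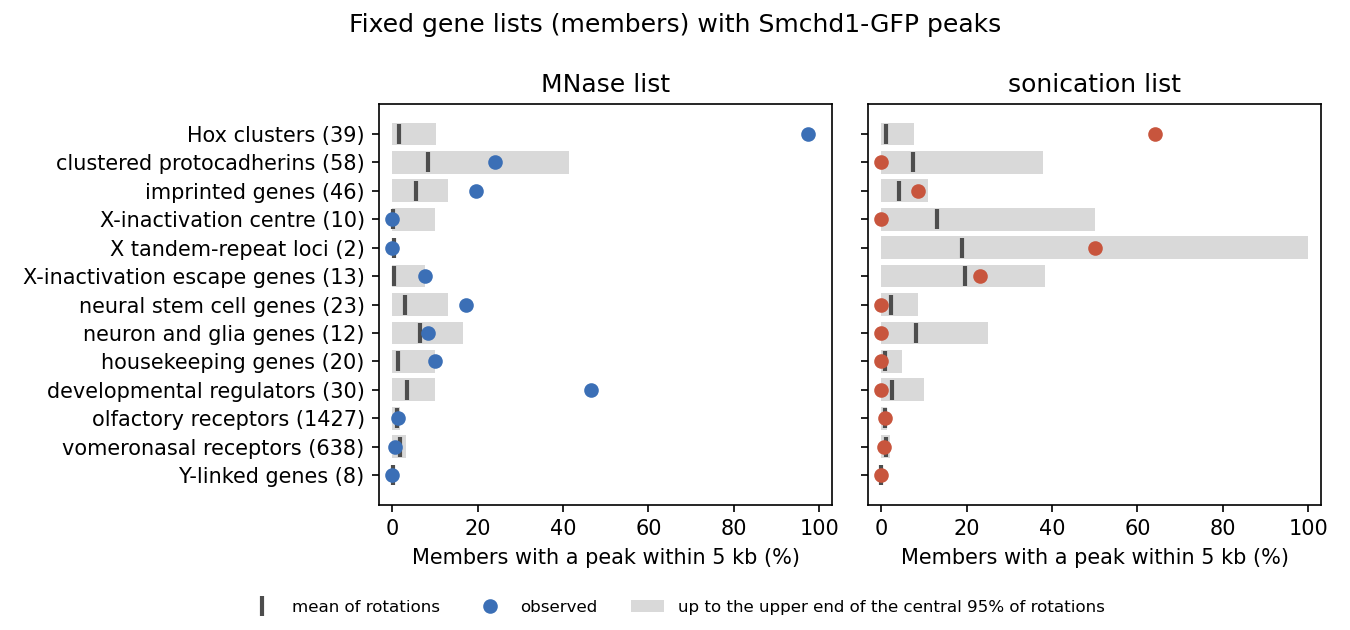
Percentage of members of each of 13 gene lists (number of members in brackets) with a peak within 5 kb in the MNase list and the sonication list; circles are observed, vertical ticks the mean of 10000 rotations, and grey bars reach the upper end of the central 95% of the rotations. Hox genes lie at 97.4% and 64.1%, and developmental regulators at 46.7% and 0%.

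MNase peaks lay at gene boundaries and in genes more often than rotated peaks did. Of 2838 peaks, 505 (17.8%) came within 1 kb of a boundary of a coding gene, against a rotated mean of 113, a ratio of 4.47 (two-sided permutation p = 0.0002, the smallest the rotations can give). Overlap with genes was found for 1634 peaks (57.6%), with a rotated mean of 1422 (two-sided permutation p = 0.0002). In all, 1151 coding genes had an MNase peak in the gene or within 5 kb. Start and end of a gene were not told apart, since the gene table carries no strand.

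The experiments shared few sites, and many of those shared lay at Hox genes. Of 2838 MNase peaks, 47 overlapped a sonication peak, with a rotated mean of 1.98 (two-sided permutation p = 0.0002, the smallest possible), and 49 of 2195 sonication peaks overlapped an MNase peak, with a rotated mean of 1.93. On the X there was no overlap, with a rotated mean of 0.0257 MNase peaks. All 23 sonication peaks in the Hox clusters overlapped an MNase peak. MNase peaks covered 82.0% of HoxA, 31.5% of HoxB, 60.8% of HoxC and 70.1% of HoxD, so much of this overlap could follow from coverage alone. Overlap within the clusters was not tested. The other 26 shared sonication peaks included sites, named after their values were seen, in Nr2f2, Tfap2a, Msx1, Evx2, Pcsk2, Grb10, Snrpn, the ion-channel subunit gene Cacng2 and the RNA-binding protein gene Celf4, and near Irx2. With peaks at the Hox clusters left out of both lists, 25 MNase peaks overlapped, with a rotated mean of 1.67 (two-sided permutation p = 0.0002).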

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

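Tests in this part that were chosen only after the result was seen are those of gene boundaries on the X, of X-wide background and of overlap by width without the Hox peaks. The X share with a reduced copy number was chosen before the data were examined, and its use as an explanation was chosen after the result was seen. Tests of the detection limit, the offset between lists and genes on the X were written down before their results. The test without Dmd, Eda and Il1rapl1 was then changed after the value of its written form was seen.

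The sonication and MNase lists stood apart because their X shares differed by 24.7 percentage points. The low MNase share was weighed further. A lower X copy number from mixed male and female cells was argued against only as far as peak number falls in proportion to copy number. The upper Wilson bound of the X share, 0.647%, lay below the 4.97% given by the X at 0.75 of its length. A peak caller with a threshold could lose more peaks than that, and the only MNase whole cell extract was female. A larger effect of copy number therefore stayed open. Fewer gene boundaries on the X were argued against too, since 2 of the 706 MNase peaks within 1 kb of any gene boundary were on the X, with an upper bound of 1.03%, where the X held 5.03% of the length near boundaries. A signal spread over the X and taken as background by the peak caller stayed open: 5 of 10 X peaks lay inside domains (exact binomial p = 0.32), too few to decide. Fragmentation and sex, the biological difference the design names, are confounded between the experiments and also stay open.

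Few autosomal sonication peaks overlapped MNase peaks, 49 of 1646. Among autosomal sonication peaks of the smallest width 3 of 1144 overlapped (0.262%), and among wider ones 46 of 502 did (9.16%), a ratio of 0.0286 (Fisher's exact test, two-sided, p = 2.93e-21), as calls near the detection limit would give. Of these 46, 23 lay in the Hox clusters; without the Hox peaks, 23 of 479 wider peaks overlapped (4.80%), and the ratio was 0.0546 (Fisher's exact test, two-sided, p = 4.41e-10, run after the result was seen). A short offset between the lists was argued against, since 4.98% of autosomal sonication peaks lay within 10 kb of an MNase peak, with an upper Wilson bound of 6.14%, below the 10% set in advance. Many narrow autosomal sonication peaks may thus be weak calls, a hypothesis that reads per library would test. Wider peaks also overlap somewhat more easily by construction. The lists differ in fragmentation and sex, so a lack of overlap alone does not mark a weak call. On the X, 41.9% of sonication peaks were wider than 300 bp, yet 0 of 549 overlapped an MNase peak.

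Sonication peaks on the X overlapped genes more often than rotated peaks. With Dmd, Eda and Il1rapl1 cut out of the X, 182 of 514 peaks lay in genes, with a rotated mean of 158 and a ratio of 1.15 (one-sided permutation p = 0.0761), so a dependence on these 3 genes stayed open. An earlier form of the test, which dropped the peaks in these genes but let rotated peaks fall in them and so was biased downward, gave 1.09 (one-sided permutation p = 0.172); it was replaced after that value was seen. A larger share of gene length in the domains was argued against: genes made up 29.4% of the domains and 31.9% of the X, and rotation within the joined domains gave a ratio of 1.24 (one-sided permutation p = 0.0207). No biological explanation was tested.

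The sonication list, from libraries labelled female, held 1 peak on Y, from 13126051 to 13126650, and the domain list held 1 domain of 165 kb on Y, from 2310001 to 2475000; both stood out as signal on a chromosome outside the comparisons. The libraries behind the domain list are not given in the sources used here.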

How the results depend on the processing

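Alternatives chosen after the data were seen were wider peaks, autosomes or X alone, peaks outside the Hox clusters and upper-score domains. For results of the comparisons and for called gene lists, 45 alternative values kept their direction and side of the threshold or stayed within their spread, 3 passed a threshold the reported value did not, 3 fell short of one, 2 reversed and 1 moved. Another 63 values belong to gene lists that were not called, of which 62 stayed uncalled; 29 of the 63 counted 0 members, so they say little about stability. Sonication protocadherins, at 0 of 58 members within 5 kb, had 22 within 50 kb, 2.67 times the rotated mean (adjusted permutation p = 0.415). Olfactory receptors came closer to passing in the sonication list. Within 50 kb, 153 of 1427 had a peak, 1.67 times the rotated mean (one-sided permutation p = 0.0081, adjusted permutation p = 0.0526). Among the 45 were the alternatives for the X shares and their difference, peaks inside domains, overlap between the lists, MNase gene boundaries and MNase peaks in genes. The 10 MNase peaks on the X alone were too few for such tests: 1 lay at a boundary of a coding gene, 4.02 times the rotated mean (4.47 times over all chromosomes), 3 lay in genes (rotated mean 3.26) and 0 on a sonication peak (rotated mean 0.0257). X shares ran from 18.7% to 31.4% in the sonication list and from 0.171% to 0.483% in the MNase list.

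For sonication peaks at gene boundaries, 8.34% lay within 5 kb (permutation p = 0.0002) and 5.47% within 1 kb of any gene (permutation p = 0.0116), both below rotated peaks. The 5.19% of wider peaks lay above them (permutation p = 0.0246). These wider peaks included all 23 in the Hox clusters, and the test was not run without those. In genes, 45.1% of autosomal sonication peaks lay below rotated peaks (permutation p = 0.0004) and 39.5% of X peaks above (permutation p = 0.022). With gene bodies alone, the lists called in the MNase data fell from 4 to 2: imprinted genes had 6 members with a peak, 2.78 times the rotated mean (3.56 with the flanks; adjusted permutation p = 0.101), and neural stem cell genes 2, 3.82 times (5.72 with the flanks; adjusted permutation p = 0.299). Housekeeping genes, at 2 members, passed with wider peaks (adjusted permutation p = 0.0338). Domains with upper scores covered 61.5% of the X. The smaller windows count fewer peaks by construction; otherwise the cause was not tested.

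Not run were thresholds and comparisons by fold enrichment, score or q, the tests on read counts with their alternatives (another tool, no filter, a replicate block, leaving out each library) and the X without unknown bases, since values per peak or library and a genome sequence were not used here. No paired analysis was possible because each list pools its libraries. Unknown depth limits every absence of a peak: it was not detected at the authors' threshold.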

Other observations

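The tests in this part were chosen after the peak lists had been seen. MNase peaks lay at many developmental transcription factor genes beyond the fixed lists. Tfap2a, Tfap2b and Tfap2c, factors of neural crest and skin, were 3 of 5 members of their family with a peak within 5 kb (adjusted permutation p = 0.0036 over 16 families, rotation test). Irx1, Irx2 and Irx5 were 3 of 6 Iroquois genes (adjusted permutation p = 0.000533), and Six3 and Six6, regulators of eye and forebrain, 2 of 4 genes of their family (adjusted p = 0.00693). Among Nkx genes 5 of 11 had a peak, Nkx2-1 included (adjusted permutation p = 0.000533), and among Fox genes 9 of 39, Foxc2 and Foxd1 included (adjusted p = 0.000533). Of the Sox genes, 2 of 15 had a peak, Sox5 and Sox17 (adjusted permutation p = 0.357).

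The hypothesis that MNase peaks lie at families of developmental transcription factors outside the fixed lists was put as over 0.5 of the families passing the rotation test. Of 16 families, 12 did, with peaks at 40 of 132 members, which is consistent with the hypothesis in the data it came from. In the sonication list 0 of 16 passed after adjustment, with peaks at 6 of 132 members, though Tfap2 (one-sided permutation p = 0.0092) and Msx (one-sided p = 0.0289) had an unadjusted p under 0.05. The difference between the lists was not tested. The rotations do not allow for the general excess of MNase peaks near genes. Of all 21779 coding genes, 1151 had an MNase peak in the gene or within 5 kb.

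Genes that escape X inactivation were asked to lie outside the broad domains more often than other genes. Inside domains were 8 of 13 escape genes (61.5%), non-coding ones included, and 524 of 954 other coding genes of the X (54.9%), and Fisher's exact test, two-sided, gave p = 0.782. Among coding genes alone the direction turned, with 4 of 9 escape genes inside (44.4%; Fisher's exact test, two-sided, p = 0.739), so the hypothesis stays open at this number of genes. Those outside were Ddx3x, 181 kb from the nearest domain edge, Kdm5c, 378 kb away, Mid1, Shroom4 and Car5b.

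Between the domains on the X, the interval from 27005001 to 34815000, with 35 coding genes, held 0 sonication peaks, and the one from 133760001 to 147345000, with 115 coding genes, held 32. How well short reads map in these intervals was not examined, so a lack of peaks need not mean a lack of binding. The MNase list held 2 peaks on Y, from 258901 to 259500 and from 11857801 to 11858400.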
